A study of Homo sapiens with 6 samples.

How the data were processed

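RNA from SW480 cells, an established line from a human colorectal adenocarcinoma, was sequenced in 6 libraries on an Illumina NovaSeq instrument. Per the labels, 3 libraries came from cells given buffer and 3 from cells given Amuc_0904, total RNA was extracted with TRIzol, and libraries followed standard Illumina protocols. The labels give no dose, exposure time or strand protocol. Neither do they say whether replicates were separate cultures, so the p-values measure only the spread between the samples as labelled.

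The authors deposited a single gene table in TPM, a within-library share scaled by transcript length, with RSEM as the quantification tool. The submitters' processing notes also name HISAT2, StringTie and edgeR, without versions or roles. They name a mouse genome build (GRCm38.p6), while the identifiers in the table are human Ensembl gene identifiers, so the annotation behind the values is not known with certainty. The table holds 60664 genes, of which 29672 were listed at 0 in every library and 20055 had no symbol. Values are rounded to 2 decimals. The deposited TPM summed to between 996107 and 997036 per library. TPM keeps no record of read number, so the depth of each library is unknown and no counting interval or detection floor is given. A value of exactly 0 can be a failed estimate, so such genes are described as listed at 0 and no fold is given for them. The strand protocol is also unknown, so values of genes that overlap another gene can hold reads from the neighbour.

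Groups followed the treatment in the labels, and the single comparison was Amuc_0904 against buffer. Values were taken as log2(TPM + 1), and genes with TPM of at least 1 in at least 3 libraries were tested, 14421 in all. Each gene was fitted with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean-variance trend, two-sided), and p-values were adjusted by the Benjamini-Hochberg method, with an adjusted p of 0.05 as the threshold. Log2 fold changes are treated minus buffer on the log2(TPM + 1) scale, which understates the change of genes at a few TPM. Folds are ratios of group mean TPM, and errors are standard deviations between libraries unless named as the standard error (SE) of the fit.

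The comparison, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Named genes were the 12 with the largest positive and the 12 with the largest negative log2 fold change among genes with a symbol, a mean of at least 5 TPM, an adjusted p under 0.05 and treated libraries all above or all below the buffer libraries. In addition, each list contributed up to 4 members past the threshold with the largest change, or, where none passed, up to 2 tested members with the highest mean. All other genes given, including further list members, were chosen after their values were seen, except the markers of other cell types, which were fixed as lists. Of the 37 fixed lists, the 32 with at least 5 tested members were compared with all other tested genes by camera in limma with a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry, also in limma, were alternatives.

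The planned primary test needs counts and was not run, because the table gives none, and the limma fit named in advance for that case was used. Other alternatives were a pseudocount of 0.1, no filter on low TPM, ribosomal protein and mitochondrially encoded genes left out with the rest rescaled, the replicate number as a block, each library left out in turn, and an adjusted p of 0.01. Further alternatives were chosen after the data were seen. In these, each library's trend with transcript GC content was removed by a loess fit with a span of 0.3, the trend with transcript length was removed in the same way, libraries were quantile normalized or centred on their median, the filter was raised to 5 TPM, libraries were weighted, genes with identical values were counted once, the pair of libraries at the ends of the first principal component was left out, and limma's treat was run against a fold of 1.2. GC content and length came from the longest transcript of each gene in GENCODE 29, which covered 14277 of the tested genes (99.0%). Gene positions are from the same release on GRCh38.

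The workflow was tested on simulated data with 14421 genes, of which 200 with a mean of at least 5 TPM were changed. It recovered 84% of genes changed 1.5-fold and 99% of those changed 2-fold, and 8.5% of its calls were unchanged genes. With no changed gene it called 0 genes and 0 lists. In these runs genes varied independently and without a trend with GC content. In the real data the estimated correlation was, for example, 0.90 among mitochondrially encoded mRNAs. The simulation thus does not show how often lists are called when their members vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.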

Results

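Gene expression was measured by RNA sequencing in SW480 colorectal cancer cells given Amuc_0904 (3 libraries) or buffer (3 libraries). The name Amuc_0904 has the form of a locus tag of the gut bacterium Akkermansia muciniphila, and the labels do not describe the preparation further. Between 14244 and 14586 genes per library had a TPM of at least 1. Mitochondrially encoded transcripts held between 9.86% and 12.8% of the listed TPM, and ribosomal protein transcripts held between 18.4% and 21.5%. The first principal component held 33.8% of the variance and placed all 3 buffer libraries on one side and all 3 treated libraries on the other, with buffer replicate 2 and Amuc_0904 replicate 3 at its ends. The order of the 6 libraries along it was also the order of their slopes of log2 expression with transcript GC content, described below. Treatment and GC content therefore cannot be told apart on this component. The labels name the question as which genes differ between the treatments.

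The named genes that rose in cells given Amuc_0904 included cytokine and chemokine genes, a protease inhibitor gene and 2 protease genes. PI3, which encodes the elastase inhibitor elafin, rose 4.67-fold, from 4.32 ± 1.03 to 20.2 ± 0.406 TPM (SD, 3 libraries per group; limma adjusted p = 0.0011). The chemokine gene CCL2 rose 2.57-fold, from 63.5 ± 3.72 to 163 ± 5.22 TPM (limma adjusted p = 0.00022), and the cytokine gene IL32 rose 2.34-fold, from 84.8 ± 4.36 to 199 ± 16.3 TPM (limma adjusted p = 0.0010). The cytokine genes CSF2 (GM-CSF), LTB (lymphotoxin beta) and EBI3 (a cytokine subunit) rose by log2 fold changes of 1.10, 1.03 and 1.04. GZMB, which encodes the cytotoxic protease granzyme B, went from 4.74 ± 0.846 to 12.7 ± 2.27 TPM, and CTSS, which encodes the lysosomal protease cathepsin S, from 12.7 ± 0.254 to 25.7 ± 1.45 TPM, with limma adjusted p of 0.013 and 0.0026. The other named genes that rose were IGFL1 (log2 fold change 1.31), the antisense transcript UGDH-AS1 (1.95), TMEM265 (0.97) and BIRC3, an inhibitor of apoptosis (0.93), with limma adjusted p between 0.0088 and 0.041.

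In the GRCh38 annotation PI3 (ENSG00000124102) lies on chromosome 20 from 45174876 to 45176544, CCL2 (ENSG00000108691) on chromosome 17 from 34255218 to 34257203, and CSF2 (ENSG00000164400) on chromosome 5 from 132073790 to 132076170. None of these 3 overlaps another annotated gene. IL32 (ENSG00000008517), on chromosome 16 from 3065297 to 3082192, overlaps 1 gene on each strand, TMEM265 overlaps 3 genes on its own strand, and UGDH-AS1 overlaps 2 on the other strand. IGFL1 and GZMB overlap 1 gene each on the other strand. Of the 12 named genes that rose, 7 stayed past the threshold without each library in turn (PI3, CCL2, IGFL1, IL32, CSF2, LTB and CTSS), and 11 did so after GC removal, centring and quantile normalization. The exception to the latter was UGDH-AS1, with a log2 fold change of 1.95 before and after GC removal (adjusted p = 0.064 after), which also lost the call without buffer replicate 3 or any single treated library. GZMB lost it without buffer replicate 2, EBI3 without buffer replicate 1 or 2, TMEM265 without buffer replicate 2 or Amuc_0904 replicate 1 or 2, and BIRC3 without any single library except buffer replicate 1 (highest adjusted p = 0.080).

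Named genes that were lower in treated cells included a stem cell transcription factor, a Wnt ligand and a ubiquitin-conjugating enzyme. UBE2S, which encodes a ubiquitin-conjugating enzyme of the anaphase-promoting complex, fell from 410 ± 21.7 to 194 ± 29.6 TPM (limma log2 fold change -1.08, SE 0.11, adjusted p = 0.0077). ASCL2, a transcription factor of intestinal stem cells, fell 2.12-fold, from 38.2 ± 3.37 TPM in buffer libraries (limma log2 fold change -1.05, SE 0.12, adjusted p = 0.0088). WNT11, a Wnt ligand gene, fell from 12.2 ± 2.26 to 5.94 ± 0.520 TPM, and LTBP3, which encodes a binding protein of latent TGF-beta, from 81.0 ± 13.7 to 45.0 ± 5.07 TPM. NDUFAF8, an assembly factor gene of respiratory complex I, fell from 228 ± 31.5 to 100.5 ± 28.1 TPM, and SWT1 from 12.1 ± 3.63 to 2.42 ± 1.30 TPM. The other named genes that fell were SPACA6 (log2 fold change -1.08), KRT10 (-0.96), MYH7B (-0.91), ZNF580 (-0.89), NANOS1 (-0.84) and ANKRD9 (2.23-fold, to 4.35 ± 0.405 TPM). Limma adjusted p for the 12 ranged from 0.0077 to 0.035.

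ASCL2 (ENSG00000183734) lies on chromosome 11 from 2268495 to 2270952 and overlaps no annotated gene, and UBE2S (ENSG00000108106) lies on chromosome 19 from 55399745 to 55407777 and overlaps 1 gene on the other strand. SWT1 and SPACA6 overlap 3 genes each on their own strand, ZNF580 overlaps 2 and MYH7B overlaps 1. On the other strand SWT1 overlaps 4 genes, ANKRD9 and MYH7B overlap 2 each, and SPACA6, KRT10, WNT11 and NANOS1 overlap 1 each. Of the 12 named genes that fell, 3 stayed past the threshold without each library in turn (UBE2S, SPACA6 and ANKRD9), and ASCL2 lost it without buffer replicate 2 (adjusted p = 0.052). The other 8 lost it without buffer replicate 2 and also without each of at least 2 other libraries, with adjusted p up to 0.14. After GC removal, centring and quantile normalization 7 of the 12 stayed past it each time, while SWT1, NDUFAF8, MYH7B, ZNF580 and LTBP3 lost it in at least 1 of these. Among the calls that GC removal ended, the log2 fold change of SWT1 was -1.98 before (SE 0.33) and -2.03 after (SE 0.36), that of NDUFAF8 -1.21 and -0.999, and that of MYH7B -0.91 and -0.72.

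**Figure D1:**
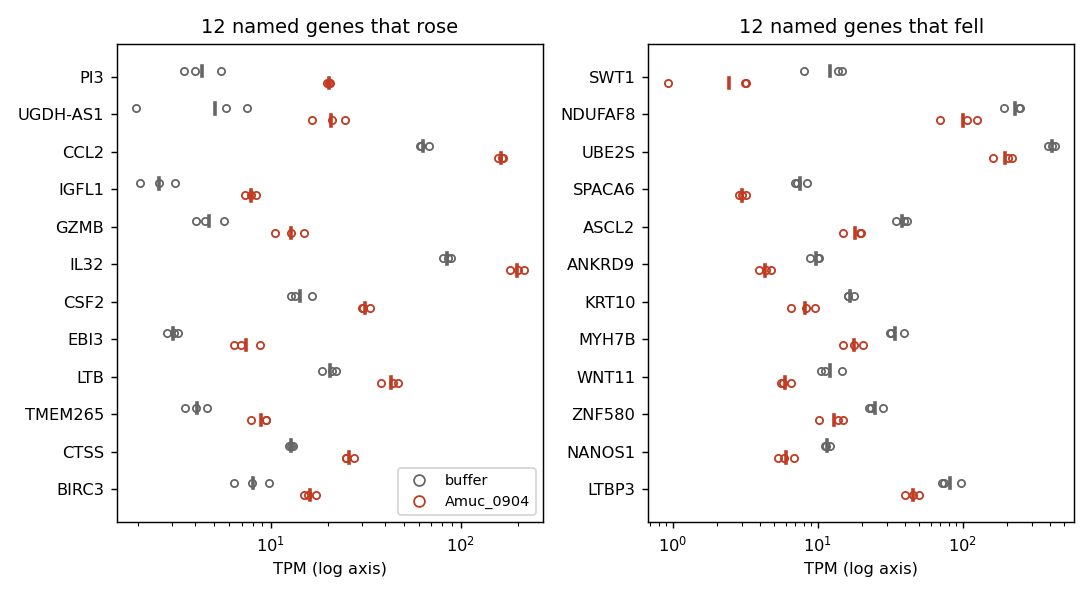
TPM (log axis) of the 12 named genes that rose and the 12 that fell in each of the 6 libraries; open circles are libraries and bars are group means, grey for buffer and red for Amuc_0904. PI3 lies between 3.49 and 5.48 TPM in buffer libraries and between 19.75 and 20.56 TPM in treated libraries.

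In all, 197 of 14421 genes passed an adjusted p of 0.05 in limma, of which 53 rose and 144 fell (73.1% fell). The median log2 fold change over the tested genes was -0.06, and 3001 genes had an unadjusted p under 0.05. With a log2 fold change of at least 1 in size on the log2(TPM + 1) scale, called a doubling or halving here, 16 genes rose and 16 fell. By the ratio of mean TPM, 17 called genes rose and 17 fell at least 2-fold, besides 3 listed at 0 throughout the buffer libraries and 3 throughout the treated libraries. The split depended on scaling: 43 rose and 42 fell (49.4% fell) with each library centred on its median, 46 rose and 56 fell after quantile normalization (54.9% fell), 48 rose and 50 fell after the trend with transcript length was removed (51.0% fell), and 78 rose and 40 fell after the GC trend was removed (33.9% fell). The count of calls fell to 55 without buffer replicate 1, 35 without buffer replicate 2, 75 without buffer replicate 3, 52 without Amuc_0904 replicate 1, 56 without Amuc_0904 replicate 2 and 112 without Amuc_0904 replicate 3. The genes with at least a doubling or halving numbered 17 without buffer replicate 2 and 21 without Amuc_0904 replicate 2. Without both libraries at the ends of the first principal component, 8 genes rose and 8 fell.

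Among the calls, 27 (13 that rose, 14 that fell) held without each library in turn, and all 27 also held after centring and after quantile normalization. GC removal could be run on the 22 of these with a GC value (12 that rose, 10 that fell), and all 22 held. Genes of this group outside the naming rule, chosen after their values were seen, included the acute phase and innate defence genes SERPINA1 (276 ± 13.2 to 461 ± 0.626 TPM, limma adjusted p = 0.0018), LCN2 (105 ± 6.79 to 174 ± 2.30 TPM, adjusted p = 0.0041) and SAA2 (495 ± 21.7 to 720.2 ± 32.7 TPM, adjusted p = 0.0088). SAA2 and the neighbouring SAA1 are near-identical copies, so reads cannot be assigned between them with certainty. The 14 that fell included 8 entries for the 5.8S ribosomal RNA with identical values, which amount to 1 measurement. The small nuclear RNA gene RNVU1-14 was listed at 4.71 ± 1.03 TPM in buffer libraries and at 0 in all 3 treated libraries, as 1 of 6 called genes listed at 0 throughout a group.

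**Figure D2:**
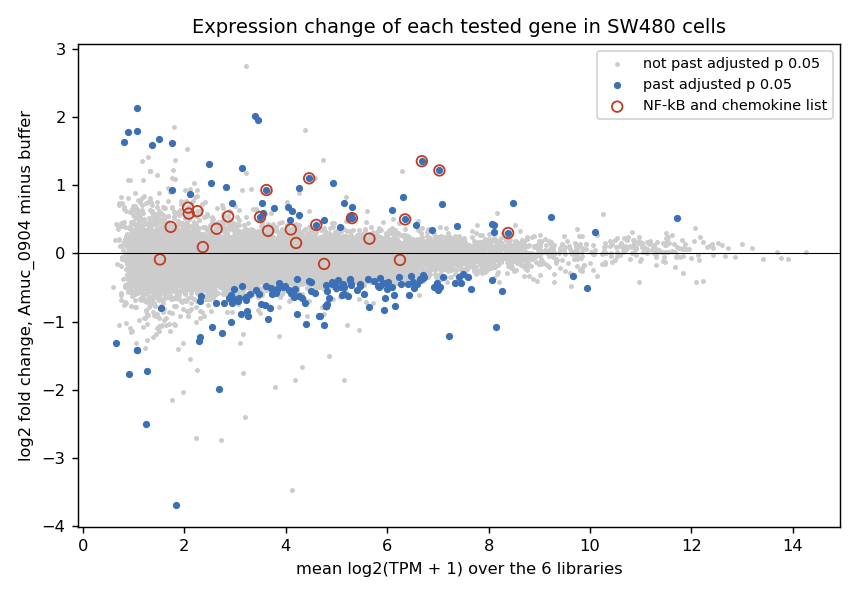
Log2 fold change (Amuc_0904 minus buffer) of each of 14421 tested genes against its mean log2(TPM + 1) over the 6 libraries; blue points passed an adjusted p of 0.05 in limma and red rings mark the 23 tested members of the NF-kB and chemokine list. Of the ringed genes, 20 lie above 0 and 3 below.

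In the NF-kB and chemokine list, of genes transcribed in response to inflammatory signals, 9 of 23 tested members rose, 0 fell and 14 did not pass, and 18 rose when adjusted over the list alone. CCL2, IL32, CSF2 and BIRC3 had the largest changes, and the other 5 that rose, named outside the rule after their values were seen, were CXCL1 (8.37 ± 0.245 to 12.6 ± 0.590 TPM), NFKBIA (32.2 ± 2.07 to 46.4 ± 1.86 TPM), SOD2, NFKB2 and IER3. Further members chosen after their values were seen were CXCL8 (2.38 TPM in buffer and 4.34 TPM in treated libraries) and TNF (log2 fold change 0.59), which did not pass (limma adjusted p = 0.076 and 0.098). CXCL1, NFKB2 and IER3 lost the call whichever single library was left out, and NFKBIA and SOD2 without any single library except Amuc_0904 replicate 3 (highest adjusted p = 0.17 among the 5). The 3 members below 0, LIF, CCL20 and TNFAIP2, did not pass. The median log2 fold change of the list was 0.42, and camera gave an adjusted p of 7.7e-20. With this preset correlation the list also passed in 8 of the 9 other splits of the libraries into 3 and 3 (adjusted p from 0.00029 to 0.037). Those splits mix buffer and treated libraries and so keep a part of any treatment difference. Passing there does not show how often the list would pass without such a difference. The NF-kB and chemokine list was the 1 list past the threshold in camera with an estimated correlation (adjusted p = 0.015). The correlation estimated for it was -0.0041, below the preset 0.01, so correlation between its members does not account for the higher p. A higher p with an estimated correlation therefore does not by itself show that the members of a list vary together. The call with an estimated correlation was lost without each single library, while the call with the preset correlation held each time. In those runs the list median lay between 0.40 and 0.49 (camera adjusted p with the preset correlation at most 1.9e-15). Adjusted p with an estimated correlation was 0.072, 0.075 and 0.070 without buffer replicates 1, 2 and 3, and 0.058, 0.085 and 0.097 without Amuc_0904 replicates 1, 2 and 3. After GC removal the median was 0.55, with 10 members that rose and an adjusted p of 0.054 with an estimated correlation.

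The MHC class I and antigen presentation list was shifted up. All 14 tested members had a positive log2 fold change, 1 rose and 0 fell, and 5 rose when adjusted over the list alone. The member past the threshold was B2M, the invariant light chain of MHC class I, which rose from 981 ± 55.8 to 1221 ± 25.1 TPM (limma adjusted p = 0.047). Chosen after their values were seen, HLA-B was at 300.2 TPM in buffer and 352 TPM in treated libraries and PSMB9, an immunoproteasome subunit gene, at 33.5 and 42.7 TPM, with adjusted p of 0.103 and 0.106. The list median was 0.19 (camera adjusted p = 4.8e-06, and adjusted p = 0.12 with an estimated correlation), and it was 0.09 without Amuc_0904 replicate 2. After GC removal the list median was 0.29, and 2 members rose (camera adjusted p = 4.8e-09, and adjusted p = 0.081 with an estimated correlation). HLA genes share much of their sequence, so their separate levels are less certain than the list median, and B2M lost its call whichever single library was left out (adjusted p up to 0.17) and after GC removal, where its log2 fold change was 0.29 in place of 0.32 (adjusted p = 0.077).

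Targets of Wnt and beta-catenin signalling were shifted down. Of 19 tested members 0 rose, 2 fell (ASCL2 and SP5) and 17 did not pass, and 2 rose and 11 fell when adjusted over the list alone. SP5, a transcription factor gene, fell from 142 ± 7.55 to 101 ± 6.64 TPM (limma adjusted p = 0.023), a call that ended without buffer replicate 2 or 3 or Amuc_0904 replicate 1 or 2 (highest adjusted p = 0.11). After GC removal the log2 fold change of SP5 went from -0.49 to -0.24 (adjusted p = 0.18), and its call also ended with centring (adjusted p = 0.059). Chosen after their values were seen, AXIN2, a negative regulator of the pathway, was at 319 TPM in buffer and 263 TPM in treated libraries (adjusted p = 0.077), and NKD1 at 61.5 and 37.0 TPM (adjusted p = 0.065). MYC and DKK1, also outside the naming rule, were the 2 members that rose when adjusted over the list alone (log2 fold change 0.21 and 0.38). The list median was -0.27 (camera adjusted p = 2.9e-04, and adjusted p = 0.35 with an estimated correlation). After GC removal the median was -0.17.

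Epithelial junction and keratin genes and cholesterol synthesis genes were also shifted down, by less. Of 17 tested junction and keratin genes 2 fell, 0 rose and 15 did not pass, and 6 fell when adjusted over the list alone. CDH1, which encodes E-cadherin, fell 1.84-fold, to 3.80 ± 0.246 TPM, and PKP3, which encodes the desmosomal protein plakophilin 3, fell from 65.8 ± 4.17 to 47.3 ± 3.89 TPM (limma adjusted p = 0.044 and 0.038). The list median was -0.19 (camera adjusted p = 0.0071, and adjusted p = 0.31 with an estimated correlation), and the call ended after GC removal (median -0.12, adjusted p = 0.063). Of 21 cholesterol synthesis genes 1 fell and 20 did not pass, and 7 fell when adjusted over the list alone. That list's median was -0.15 (camera adjusted p = 0.0019, and adjusted p = 0.35 with an estimated correlation). After GC removal the cholesterol synthesis list kept its call, with a median of -0.13 (camera adjusted p = 1.7e-04, and adjusted p = 0.10 with an estimated correlation). CDH1 and PKP3 each lost their call whichever single library was left out, and also after GC removal, where PKP3 went from a log2 fold change of -0.47 to -0.22 (adjusted p = 0.11) and CDH1 from -0.73 to -0.68 (adjusted p = 0.054).

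Of 20 tested G2 and mitosis genes 0 passed over all genes and 3 fell when adjusted over the list alone (PLK1, AURKB and BIRC5, named after their values were seen). The list median was -0.12 (camera adjusted p = 0.013, and adjusted p = 0.62 with an estimated correlation). The median was -0.07 without Amuc_0904 replicate 2 and -0.20 without Amuc_0904 replicate 3. This call ended without buffer replicate 1, Amuc_0904 replicate 1 or Amuc_0904 replicate 2 (highest adjusted p = 0.18) and with each library centred on its median (adjusted p = 0.077). After GC removal the list kept a median of -0.12 and its call (camera adjusted p = 1.6e-05, and adjusted p = 0.17 with an estimated correlation). All 6 tested members of the colorectal epithelial identity list had negative log2 fold changes and 0 passed, while 3 fell when adjusted over the list alone. As fixed, this list shares EPCAM, KRT8, KRT18 and KRT19 with the epithelial junction and keratin list, so the lists are not independent. CDX2, an intestinal transcription factor, was at 28.0 ± 5.22 TPM in buffer and 18.7 ± 0.528 TPM in treated libraries (limma adjusted p = 0.077). The median was -0.18 (camera adjusted p = 0.018, and adjusted p = 0.31 with an estimated correlation), and the call ended after GC removal (adjusted p = 0.24) and after centring (adjusted p = 0.077).

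The other 4 lists past the threshold were shifted up, with no single member past it over all genes. The metallothionein list, of metal-binding proteins, had 3 of 6 members that rose when adjusted over the list alone, led by MT2A (3779 ± 280.4 TPM in buffer and 4912 ± 229.6 TPM in treated libraries, limma adjusted p over all genes 0.051), and a median of 0.19 (camera adjusted p = 0.0024, and adjusted p = 0.33 with an estimated correlation). Cytosolic ribosomal proteins had 20 of 25 members above 0 and a median of 0.08 (adjusted p = 1.1e-04, and adjusted p = 0.58 with an estimated correlation), and the call ended after quantile normalization (adjusted p = 0.59). Ribosome biogenesis had 15 of 20 above 0 and a median of 0.09 (adjusted p = 6.7e-04, and adjusted p = 0.31 with an estimated correlation). Nuclear-encoded oxidative phosphorylation had 19 of 23 above 0 and a median of 0.06 (adjusted p = 0.0019, and adjusted p = 0.50 with an estimated correlation). Single libraries moved these last 3 medians: without Amuc_0904 replicate 3 they were 0.12, 0.04 and 0.10 in the order given, and without Amuc_0904 replicate 1 that of ribosomal proteins was 0.05. None of the members of these last 3 lists passed when adjusted over the list alone. After GC removal MT2A passed over all genes (log2 fold change 0.49, limma adjusted p = 0.0375), and the metallothionein median was 0.28. The medians of the last 3 lists were then 0.15, 0.14 and 0.10 in the order given. None of the 4 lists passed after GC removal with an estimated correlation (camera adjusted p from 0.081 to 0.57).

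**Figure D3:**
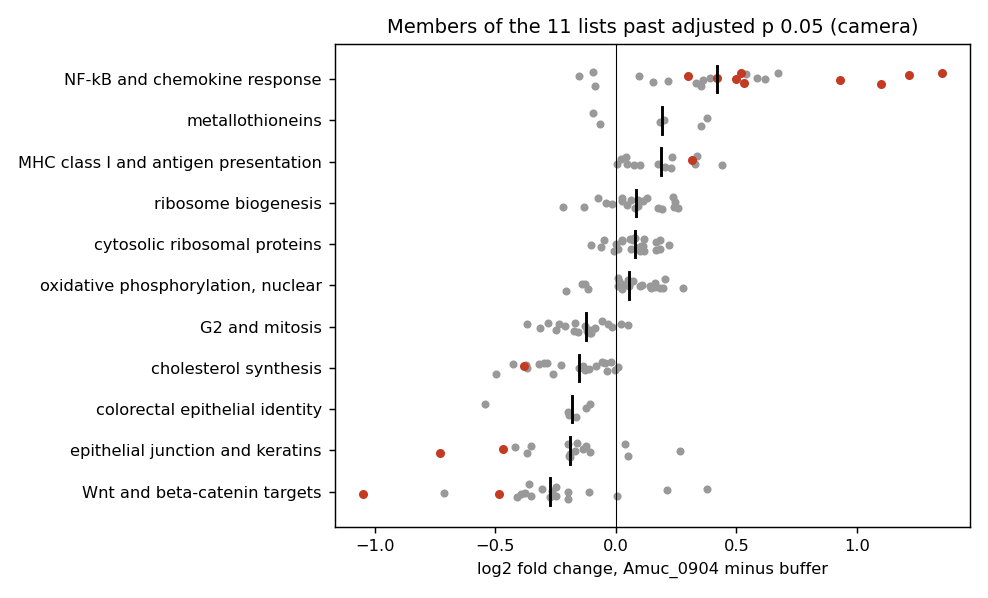
Log2 fold change (Amuc_0904 minus buffer) of the tested members of the 11 lists past an adjusted p of 0.05 in camera; red points passed an adjusted p of 0.05 in limma over all genes, grey points did not, and black bars are list medians, from 0.42 for the NF-kB and chemokine list to -0.27 for Wnt and beta-catenin targets. Points are spread vertically at random within a list.

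Among lists that did not pass in camera, a few single members changed. In the immediate early and AP-1 list 2 of 22 fell, IER5 (50.9 ± 2.22 to 36.5 ± 1.22 TPM) and ETV4 (113 ± 5.88 to 86.2 ± 1.85 TPM). In the ATF4 and integrated stress response list 2 of 17 fell, the amino acid transporter gene SLC7A5 (240.5 ± 22.3 to 166.8 ± 6.83 TPM) and the transcription factor gene CEBPB (25.8 ± 1.69 to 15.3 ± 3.02 TPM). NT5E in the list of YAP and TEAD targets rose 1.65-fold, to 19.8 ± 1.18 TPM, as 1 of 13, and P4HA2, a collagen prolyl hydroxylase gene in the hypoxia response list, rose from 80.7 ± 3.63 to 108 ± 8.38 TPM, as 1 of 15. CTSD, a lysosomal protease gene, fell from 218 ± 12.3 to 170.8 ± 8.99 TPM, as 1 of 19 in the lysosome and autophagy list, and LTBP3 was the 1 of 15 that fell in the list of TGF-beta and SMAD targets. Limma adjusted p for these 8 genes ranged from 0.020 to 0.048, and each lost its call when any of at least 4 single libraries was left out. GC removal ended the calls of CTSD (log2 fold change -0.35 before, -0.13 after, adjusted p = 0.19), ETV4 (-0.39 and -0.20, adjusted p = 0.15) and CEBPB (-0.73 and -0.48, adjusted p = 0.14), and centring ended all 6 calls of genes that fell (adjusted p from 0.053 to 0.12). When adjusted over the list alone, 3 fell in the immediate early list, 5 in the ATF4 list, 3 in the TGF-beta list and 2 in the lysosome list, and 2 rose in the mesenchymal and EMT list and 1 in each of the YAP, hypoxia and lysosome lists. Camera adjusted p for these 7 lists ranged from 0.15 to 0.78.

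No member passed in the other 14 tested lists, where camera adjusted p ranged from 0.097 to 0.90. The 14 tested interferon-stimulated genes had a median of 0.01 (camera adjusted p = 0.28), with ISG15 at 113 ± 8.07 TPM in buffer and 119.8 ± 8.96 TPM in treated libraries. The 19 tested p53 targets had a median of -0.0038 (adjusted p = 0.90), and the 21 genes of the death receptor and apoptosis list a median of 0.02 (adjusted p = 0.097). Adjusted over the list alone, 0 passed in these 3. In that adjustment 5 of 11 fatty acid synthesis genes fell and 1 rose, 3 of 15 cytosolic heat shock genes fell, 3 of 15 NRF2 and oxidative stress genes fell and 1 rose, 1 of 20 S phase genes fell and 1 of 6 MondoA targets rose. None passed among ER chaperones, glycolysis, mitochondrially encoded mRNAs, Toll-like receptor and inflammasome sensing, glycosylation and sialic acid, or replication-dependent histones. For p53 targets, ER chaperones, glycolysis, hypoxia response, mitochondrially encoded mRNAs, mesenchymal genes and histones the median was below 0 while camera, which compares with all other genes, pointed up, and for heat shock genes the mean (-0.05) and median (0.01) differed in sign. After GC removal the death receptor and apoptosis list passed in camera, shifted up (median 0.095, adjusted p = 0.042). The fatty acid synthesis list then also passed, shifted down (median -0.11, adjusted p = 0.046). Neither passed after GC removal with an estimated correlation (camera adjusted p = 0.35 and 0.43).

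Few markers of other cell types were expressed. PTPRC and TYROBP, found in most leukocytes, were listed at 0 in all 6 libraries. Of 12 leukocyte markers 3 were tested and 0 passed, with CD68, a lysosomal protein gene of macrophages that other cells also express, at 1.42 ± 0.295 TPM in buffer and 2.84 ± 0.442 TPM in treated libraries (limma adjusted p = 0.077). LAPTM5 was at 10.3 ± 0.622 and 12.6 ± 0.982 TPM (adjusted p = 0.16). Of 10 fibroblast markers 2 were tested (COL6A3 and COL1A1) and 0 passed, of 7 endothelial markers 0 were tested, and of 16 markers of other cultured lines 2 were tested (HBA1 and PMEL) and 0 passed. Of 20 genes for intestinal differentiation and mucins, 3 were expressed enough to be tested and 0 passed. Adjusted over the list alone, 2 leukocyte markers rose, 1 fibroblast marker fell and 1 gene for intestinal differentiation fell.

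Changes ran with the GC content of transcripts. Across genes, which are not independent replicates, Spearman's rho of log2 fold change and GC content was -0.43. Genes that fell had a median GC content of 59.4%, genes that rose 50.6% and all tested genes 49.2%. Libraries differed within groups too: the slope of log2 expression per 10 points of GC content was 0.093 in buffer replicate 2 but 0.0045 in buffer replicate 1, and -0.11 in Amuc_0904 replicate 3 but 0.0021 in Amuc_0904 replicate 2. Among the 1428 genes with the highest GC content 3 rose and 44 fell, and among the 1428 with the lowest 1 rose and 3 fell.

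**Figure D4:**
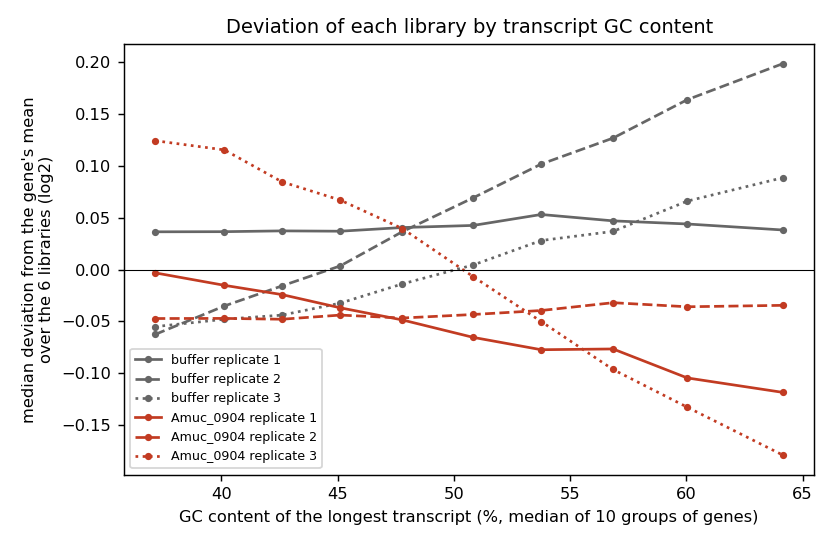
Median deviation of each library from the gene's mean over the 6 libraries (log2) against the median GC content (%) of each of 10 groups of tested genes of near-equal size; grey lines are buffer and red lines Amuc_0904 libraries. In the group with the highest GC content buffer replicate 2 lies at 0.20 and Amuc_0904 replicate 3 at -0.18.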

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

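The alternatives with no filter beyond genes at 0 in every library, a pseudocount of 0.1, gene classes left out, the replicate block, single libraries left out, an adjusted p of 0.01, the estimated correlation and fry were planned, and the rest were chosen after the data were seen. The planned count-based alternatives (other size factors, DESeq2, voom with weights, robust edgeR fits, CPM filters and glmTreat) could not be run because the table gives TPM only. In no alternative did a named gene or list past the threshold change sign while passing it. With a pseudocount of 0.1 the calls numbered 184, and with identical genes counted once 181. Of the 197 calls, 53 up and 144 down, leaving out single libraries gave between 35 and 112 calls, 15 to 38 up and 20 to 74 down, 17 to 30 with a doubling or halving in place of 32, and 10 to 14 lists in place of 11. The cause was not tested, beyond the smaller number of libraries. With no filter on low TPM 9 genes passed (7 up, 2 down, 5 with a doubling or halving) out of 30992 tested. With a minimum of 5 TPM, 432 passed (354 down), of 10292 tested, and with library weights 427 (89 up, 338 down). GC removal gave 118 calls, 40 down and 21 with a doubling or halving, of which 81 were among the 197. Quantile normalization gave 102 (56 down), centring on the median 85 (42 down), removal of the trend with transcript length 98 (50 down), and leaving out ribosomal protein and mitochondrial genes 92 down. Without both libraries at the ends of the first principal component 16 genes passed, 8 up and 8 down, and 11 with a doubling or halving. At an adjusted p of 0.01 the calls were 29. Limma's treat against a fold of 1.2 called 16 genes in place of the 32 with a log2(TPM + 1) change of at least 1. Camera with an estimated correlation called 1 list, and fry, which does not compare a list with other genes, called 8. Those included the ATF4 and NRF2 lists, both down (fry adjusted p = 0.028 and 0.026). Fry did not call G2 and mitosis, nuclear-encoded oxidative phosphorylation, ribosomal proteins, ribosome biogenesis or metallothioneins (fry adjusted p from 0.084 to 0.34). For the changes named here the cause was not tested.

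With the replicate number as a block 80 genes passed (27 up, 53 down). The numbers do not pair the libraries by the values: deviations of libraries with the same number correlated across genes at -0.03, 0.08 and -0.09. The adjusted p of the NF-kB and chemokine list with an estimated correlation was 0.55 with the block, and from 0.014 to 0.55 over all alternatives. Depth is not recorded in TPM, so what low levels can show is not known.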

Other observations

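Other genes outside the fixed lists, all chosen after their values were seen, also changed. IL23A, a subunit of interleukin 23, rose from 7.95 ± 0.572 to 13.9 ± 0.814 TPM, and TNFRSF6B, a decoy receptor for FAS ligand, from 59.1 ± 7.25 to 106 ± 16.3 TPM (limma adjusted p = 0.014 and 0.027, each higher in 3 of 3 treated libraries than in any buffer library). The transcription factor gene ETS1 rose from 30.5 ± 0.769 to 44.3 ± 1.43 TPM, PERP, a desmosomal gene, from 54.0 ± 1.44 to 84.6 ± 4.68 TPM, and STEAP1 from 30.6 ± 2.27 to 49.4 ± 2.49 TPM (adjusted p = 0.013, 0.0078 and 0.0094). Without buffer replicate 1, buffer replicate 2 or Amuc_0904 replicate 1, the calls of IL23A, TNFRSF6B and ETS1 ended (adjusted p from 0.053 to 0.13), and that of TNFRSF6B also without Amuc_0904 replicate 2 (adjusted p = 0.074). KLC1, a kinesin light chain gene, fell from 91.8 ± 9.94 to 53.4 ± 3.69 TPM (adjusted p = 0.011).

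Of the tests below, those on GC content and on other splits of the libraries were set before their results were seen, and those on leukocyte RNA, the preparation, scaling, transcript length and matched gene lists were chosen afterwards.

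The NF-kB and chemokine list rose. A GC-dependent difference between libraries as the cause would have brought its median under 0.1, but the median was 0.55 after GC removal and lay between 0.51 and 0.57 without each single library. This outcome was largely fixed beforehand. The median GC content of the list was 53.1%, against 49.2% for all tested genes, and log2 fold changes fell with GC content. The medians of 10000 random lists matched on expression and GC content centred on -0.09, so the GC trend ran against the rise of the list. RNA from leukocytes would have brought general leukocyte transcripts, but the highest level of PTPRC, TYROBP, LYZ, CD3E or CD3D in any treated library was 0.64 TPM, against a rise of CCL2 by 99.95 TPM, while 2 of 3 tested members of the fixed leukocyte list rose when adjusted over that list alone (CD68 from 1.42 to 2.84 TPM, LAPTM5 from 10.3 to 12.6 TPM). The design holds 0 control groups other than buffer, so an effect of Amuc_0904 and that of another component of the preparation, such as bacterial endotoxin, cannot be told apart, and both stay open. TLR4, the endotoxin receptor, was listed between 1.05 and 2 TPM, which excludes neither.

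More genes fell than rose. After GC removal the share of calls that fell was 33.9%, on the far side of the range of 40 to 60% set for a GC cause, and between 15.8% and 41.2% without each single library. Centring alone gave 49.4% and removal of each library's trend with transcript length gave 51.0%, but these and GC removal all bring the median change to about 0, which in part fixes the split, and leaving out ribosomal protein and mitochondrial genes gave 63.4%. The prediction for a length cause also asked for a share well apart from that of centring alone, which 51.0% against 49.4% did not meet. The median transcript of genes that fell had 2893 bases, against 3245 for all tested genes, which a loss of signal from long transcripts would not give. Genes that rose were shorter still (1365.5 bases), and rho of log2 fold change with length across genes was -0.085. These values point both ways, so length is not excluded. Scaling, GC content and transcript length cannot be told apart from a true excess of falling genes, which may reflect library preparation as much as treatment.

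Wnt and beta-catenin targets fell as a list. After GC removal the median was -0.17 (from -0.21 to -0.13 without each single library), between the bounds of -0.1 and -0.2 set for and against a GC cause, so a part of the shift and GC content cannot be told apart. As the whole cause GC content is argued against, since 0.03% of 10000 random lists matched on expression and GC content had a median as low, although this test was chosen when the value was known. Such lists ignore that targets vary together, with an estimated correlation of 0.18. The camera adjusted p with that correlation was 0.35, a rise that correlation need not account for in full. Variation between the libraries in the pathway thus stays open beside an effect of Amuc_0904.

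The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. Every split but the real one mixes buffer and treated libraries. Such a split keeps a part of any treatment difference and moves the rest into the spread within groups. Gene counts and list calls in the other splits are therefore in part fixed beforehand and do not show what no treatment difference would give. For genes past the threshold 1 of the 10 splits, the real one, gave as many as 197, and the highest other gave 1. For genes with a doubling or halving 1 split, the real one, gave 32, and the highest other gave 1. For lists 1 split, the real one, gave 11, and the highest other gave 9. The NF-kB and chemokine list passed with the preset correlation in 8 of the 9 other splits (adjusted p from 0.00029 to 0.037). With an estimated correlation the real split called 1 list and every other split 0.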
